A study of Magallana gigas with 59 samples.

How the data were processed

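Total RNA of the digestive gland, the gonad and the oocytes of Pacific oysters was measured on 1-colour (Cy3) Agilent arrays made for this species, with 31918 probes of 60 bases designed on expressed sequence tags (ESTs). There were 59 arrays on 22 slides, scanned on 5 days. Days are numbered here in order of scanning, and slides in order of their barcodes. Each array held the RNA of 1 tissue of 1 oyster, or the oocytes of 1 female. The labels call the adult oysters female.

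The authors deposited the scanner software's table of each array. Per the file headers, the images were read with Feature Extraction 10.7.3.1, while the series' design text names version 6.1. The value used was the processed signal, a background-subtracted fluorescence intensity that the software wrote, per the file headers. The authors also deposited a table of normalized values on a log2-like scale. The submitters' processing notes name limma and Agilent Feature Extraction, without versions or steps. The columns of that table followed the logarithm of the median signal, but their normalization and centring are not given in the sources used here. Their medians lay between 6.67 and 7.38 in the 26 digestive gland columns, between 6.60 and 7.92 in the 25 gonad columns and between 6.05 and 6.27 in the 8 oocyte columns. That table served as an alternative only.

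From the processed signal, log2 values were taken and each array's 75th percentile over the non-control probes was subtracted, so a value of 0 is the 75th percentile of that array. Control spots were left out. Spots that the software marked as non-uniform or as population outliers, 1 to 52 per array, were left out as missing values. A probe was tested where it was marked well above background on at least as many arrays as the smallest group of the fit held, which is 5 for the digestive gland and gonad fits and 3 for the oocyte fit. No spot was saturated. Between 51.9% and 73.1% of the probes were well above background on an array, which limits the measurement of dim transcripts, and the number of arrays limits the precision. The 34 sequences printed at 2 places gave a median difference of 0.061 log2 between the places on an array, over the 33 sequences with enough values.

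Groups were taken from the labels, giving 8 groups of adult tissue and 2 of oocytes. Linear models were fitted with limma 3.58.1 in R 4.3.3 (lmFit, then variances moderated with squeezeVar), with Benjamini-Hochberg adjustment over the probes tested and a threshold of 0.05 on the adjusted p. The digestive gland fit held all 26 arrays of that tissue, the gonad fit all 25, the oocyte fit the 8 oocyte arrays, and comparisons between tissues all 51 adult arrays. Before the data were examined, 12 comparisons were fixed, together with their tests, filter and alternatives. After the data were seen, 3 comparisons were added: the week change of the exposed oysters in each tissue, and the difference between the tissues in the week change of the controls. Scan day as a term, the submitters' table, the omission of slide 2, the array's 75th percentile signal as a term and the probe sets described next were also added after the data were seen.

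The files name each probe by its EST and give no description. None of the probes matched the reference table of gene symbols (0 of 31918), so the gene lists fixed beforehand were not applied, no probe was given a gene name and no genome position is stated. Probes are named by their EST. The rule fixed beforehand allows at most 2 higher and 2 lower unnamed probes per comparison: those with the largest change among the probes past the threshold, or, for an exposure comparison with fewer than 12 such probes, the 1 with the smallest p in each direction, given as values. The second part of this choice was narrowed to 1 probe per direction after it was seen that exposure gave hardly any call. In place of gene lists, 2 probe sets were chosen from the digestive gland and oocyte arrays alone, with no gonad array taking part: probes with an adjusted p under 0.05 and a difference of over 2 log2. The oocyte-high set held 4221 probes and the gland-high set 4335, of 23729 tested. The mean of each set was taken per array and compared between gonad groups with two-sided exact permutation tests, adjusted over the 8 tests. The sets were also tested with limma's camera, with the correlation preset at 0.01 or estimated, and with fry.

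Where a probe was not well above background on any array of a group, the ratio is a lower bound, and in comparisons of more than 2 groups no size is given. The bound sets the brighter group's mean against the mean of, per array, the higher of the dim probe's own value and the lowest value among the probes well above background. It covers the background only and not the sampling error. Changes of probes that only some arrays of a group measured are fitted values and rest partly on background.

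The alternatives were normexp background correction (offset 50), quantile normalization, no filter on dim probes, the slide as a block (random in the adult tissues, fixed in the oocytes), array weights, only the 2 groups compared, blocks by replicate number or oyster, and leaving out each array in turn. Normexp was planned on all spots. That correction was run and its results were seen: a few spots with a non-uniform local background drove it on several arrays, and the interquartile range of an array's log2 values fell as low as 0.077, against 4.65 to 6.21 in the main setting. A normexp correction without the spots whose local background the software marked as non-uniform was then added, with a range of 2.23 to 3.84. Both are given, and normexp without further words means the added one. The gene list tests with their own alternatives were not run, for want of gene names.

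The labels give the digestive gland and the gonad of a week and treatment the same replicate numbers, for 25 pairs. Whether these are the same oysters was checked on the deviations of each array from its group mean, over 16248 probes. Every pair correlated, with r between 0.44 and 0.76 across probes (mean 0.56), while arrays of different numbers in the same week and treatment had a mean r of -0.10. All 50 paired arrays correlated best with the array of their own number in the other tissue. The numbers were therefore read as oysters, and the fit with oyster as a block is given beside a comparison between tissues where it changed a call or moved a count by over 1.5 times.

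The fitting steps were tested on simulated data drawn from the probes' own means and spreads, with 200 probes changed by a known amount in each of 3 draws. For the week 8 gonad comparison, simulated on 24347 probes, 10.7% of the probes changed by 1 log2 were called, 57.5% of those changed by 2 log2 and 76.3% of those changed by 3 log2. For the oocyte comparison, simulated on 19192 probes, these shares were 0% at 1 log2, 41.5% at 2 log2 and 72.2% at 3 log2. The simulated arrays varied independently, which real arrays did not.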

Results

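The study kept adult Pacific oysters in hatchery conditions through a reproductive cycle, with or without polystyrene microspheres of 2 and 6 µm at 32 µg per litre, to ask how the beads affect physiology and reproduction. Oysters were sampled after 2 and 8 weeks. Digestive gland was measured in 5 control and 7 exposed oysters at week 2 and in 6 control and 8 exposed oysters at week 8. Gonad was measured in 5 control and 7 exposed oysters at week 2 and in 5 control and 8 exposed oysters at week 8. Oocytes were measured from 5 control and 3 exposed females. The share of probes well above background was 69.0% ± 2.0 (SD, n = 5) in week 2 control gonads and 60.4% ± 4.0 (SD, n = 5) in week 8 control gonads. It was 66.0% ± 3.9 (SD, n = 8) in week 8 exposed gonads and 56.4% ± 4.3 (SD, n = 5) in control oocytes.

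Tissue set the main difference among the arrays. The first principal component, with 35.5% of the variance over 27653 probes, ran from the digestive gland through week 2 gonads and week 8 gonads to the oocytes. Its mean was -126 in week 2 control digestive glands, -12.2 in week 2 control gonads, 120 in week 8 control gonads and 277 in control oocytes. Of 26645 probes tested, 7146 were higher and 6863 lower in gonad than in digestive gland.

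Of the 4 probes named for the difference between the tissues, 3 ran into the background on the dim side. CU988676 (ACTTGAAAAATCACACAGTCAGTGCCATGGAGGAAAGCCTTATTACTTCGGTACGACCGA) had a mean of 4.32 log2 in digestive gland and was lower in gonad, with an adjusted p of 5.6e-28. It was well above background in 26 of 26 digestive glands and 9 of 25 gonads, and in 0 of 5 week 8 control gonads. CU991908 was well above background in 25 of 26 digestive glands and 1 of 25 gonads, with an adjusted p of 1.7e-23. No size is given for these 2 probes, since the gonad side is background in at least 1 group. EW778967 was higher in gonad by 5.86 ± 0.51 (SE) and was measured in all 25 gonads and 9 of 26 digestive glands. ES789346 was well above background on all 51 adult arrays and was higher in gonad by 5.14 ± 0.52. Within scan days the difference gave 7380 probes on day 2, 5658 on day 3 and 11615 on day 4, and with day as a term 14432.

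Gonads changed widely between weeks 2 and 8, during rearing that was meant to induce gamete formation. In control gonads 3347 probes rose and 3649 fell of 24619 tested, 28.4% of them. CU989573 (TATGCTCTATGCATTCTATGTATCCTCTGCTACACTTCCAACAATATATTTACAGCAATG) had the largest rise, from -2.71 ± 3.85 (SD, n = 5) to 5.50 ± 0.49 (SD, n = 5) log2 relative to the 75th percentile, with an adjusted p of 0.00048. AM861096 rose from -4.96 ± 1.65 to 2.93 ± 0.59, with an adjusted p of 1.2e-06. Both were well above background in 5 of 5 gonads at week 8 and 3 of 5 at week 2. CU998573 fell from 0.29 ± 3.81 to -5.70 ± 2.76 and CU999135 from 2.49 ± 2.52 to -3.50 ± 3.63, with adjusted p of 0.047 and 0.035. At week 8 these were well above background in 1 of 5 and 3 of 5 control gonads.

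Exposed gonads also changed between the weeks: 3800 probes rose and 3415 fell. Of these, 2660 rose and 2276 fell in the controls too, against 517 and 506 for independent lists, and 3 probes were called in opposite directions. CU989573 again had the largest rise, from -3.92 ± 3.78 (SD, n = 7) to 4.72 ± 0.64 (SD, n = 8), and AM860221 rose from -2.75 ± 4.20 to 5.25 ± 0.52. CU994639 fell from 3.47 ± 1.96 to -2.94 ± 2.36 and CU684146 from 2.36 ± 3.01 to -3.67 ± 3.01. On the lower side CU989573 was well above background in 3 of 7, AM860221 in 4 of 7 and the falling probes each in 5 of 8 exposed gonads.

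All week 2 control gonads were scanned on day 3 and no week 8 control gonad was, so in the controls no single day held both weeks. With day as a term, resting on the exposed arrays, 1641 probes passed in the controls and 6458 in the exposed gonads. Over the 6996 probes called in the controls, the median size of the change was 1.69 log2 without and 1.37 with that term, and the median SE rose from 0.39 to 0.55. Within day 4, which held 3 exposed gonads of week 2 and 5 of week 8, 1322 probes passed. The median ratio to the change over all days was 0.875, over called probes that the day 4 arrays had helped to choose. Days 2 and 3 each held a single exposed gonad of week 8, too few for a value. The median change over all tested probes in the controls was -0.17 log2 in the main scaling, -0.02 after quantile normalization, 0.04 in the submitters' table and 0.30 with normexp, and in exposed gonads it was 0.03 in the main scaling and 0.23 with normexp. The share of calls that rose was 47.8% in the main scaling and 63.8% with normexp.

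The group means of the probe sets in gonads lay between those of gland and oocytes. The oocyte-high set, 4221 probes brighter in oocytes than in digestive gland, had a mean of -0.95 ± 0.38 (SD, n = 5) in week 2 control gonads and 0.20 ± 0.29 (SD, n = 5) at week 8. It lay at -1.60 ± 0.11 in week 2 control digestive glands and at 1.43 ± 0.09 in control oocytes. The rise of 1.15 log2 in the controls had an exact permutation adjusted p of 0.016 (raw p 0.0079, the smallest that 5 against 5 allows). The gland-high set, 4335 probes, fell by 1.43 log2 in the controls with the same p, from -0.89 ± 0.33 to -2.32 ± 0.21. Of the 4172 oocyte-high probes tested in gonads, 2158 rose and 19 fell in the controls, and of the 4239 gland-high probes 14 rose and 2154 fell. In exposed gonads the oocyte-high mean rose by 1.17 and the gland-high mean fell by 1.07, both with an exact permutation adjusted p of 0.0012. Within day 4 these changes were 0.97 and -0.90. With day as a term the changes were 1.24 ± 0.30 (SE) and -1.32 ± 0.29 in the controls and 1.21 ± 0.18 and -1.05 ± 0.18 in exposed gonads.

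**Figure D1:**
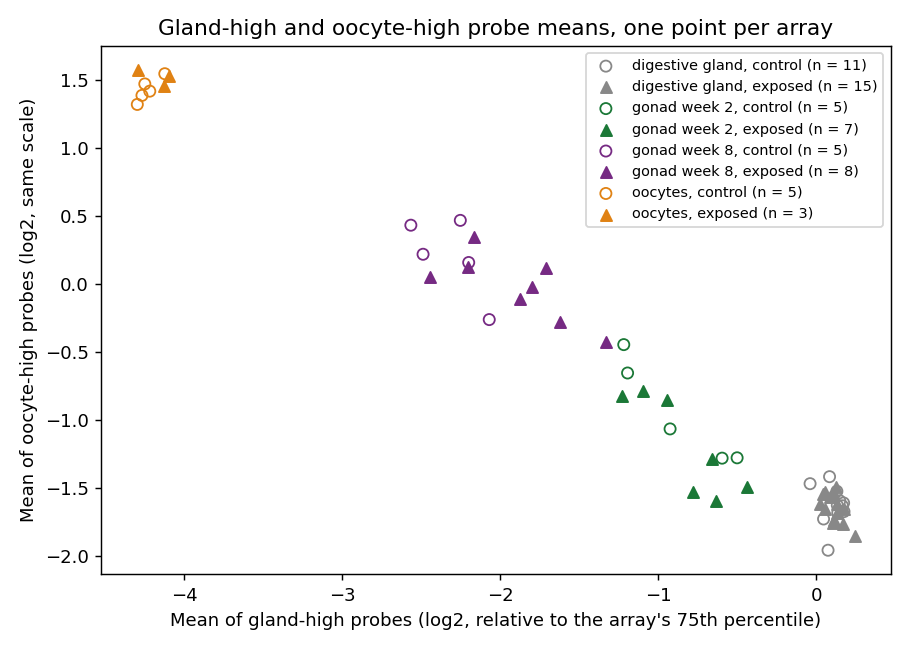
Mean of the gland-high probes (horizontal axis) and of the oocyte-high probes (vertical axis) on each array, in log2 relative to that array's 75th percentile, with open circles for controls and filled triangles for exposed oysters. On the horizontal axis the gonads reach up to -0.44, below every digestive gland array (lowest -0.04), while on the vertical axis 3 exposed week 2 gonads, from -1.60 to -1.50, lie among the glands; the sets were chosen on the gland and oocyte arrays.

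The digestive gland changed less between the weeks. In controls 47 probes rose and 38 fell of 24279 tested. AM866463 rose by 4.47 ± 0.71 log2 (SE) and FP002432 by 4.35 ± 0.66, while ES789502 fell by 5.72 ± 0.98 and CU989410 fell by 4.24 ± 0.76, with adjusted p between 0.0026 and 0.0082. On the lower side AM866463 was well above background in 4 of 5, FP002432 in 2 of 5, ES789502 in 2 of 6 and CU989410 in 6 of 6 control glands. All of these sizes but the last rest partly on background. In exposed oysters 68 probes rose and 186 fell. AM866463 rose there by 4.00 ± 0.61 and CU989573 by 3.81 ± 0.88, and ES789502 fell by 4.77 ± 0.84 and CU684359 fell by 5.20 ± 0.86. On the lower side AM866463 was well above background in 5 of 7 and CU989573 in 3 of 7 exposed glands. For ES789502 this was 6 of 8 and for CU684359 1 of 8, so these sizes also rest partly on background. No scan day held both weeks of the control glands. With day as a term 5 probes passed in controls and 86 in exposed oysters. Within day 4, which held 2 exposed glands of week 2 and 4 of week 8, 11 passed, of which 10 rose and 1 fell. The median ratio to the changes over all days was 0.972, over called probes that the day 4 arrays had helped to choose, so this ratio is partly fixed by the choice. Day 2 held a single exposed gland of week 2, too few for a value. The rising share of the control calls was 55.3% in the main scaling, 67.6% with normexp and 71.2% in the submitters' table. That of the exposed calls was 26.8%, 13.1% and 35.5% in the same order. Leaving out single arrays gave 47 to 131 in controls, with 47 without the slide 2 array (control 1) or week 2 control 17 and 131 without week 8 control 11. In exposed oysters it gave 118 (without week 8 exposed 34) to 592 (without week 8 exposed 27).

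The week change itself differed between the tissues. In controls it was higher in gonad than in digestive gland for 2011 probes and lower for 1624, of 26645 tested. AM855379 rose in control gonads from -1.33 ± 0.93 (SD, n = 5) to 5.05 ± 0.51 (SD, n = 5), against 1.96 ± 0.87 (SD, n = 5) and 3.12 ± 0.73 (SD, n = 6) in digestive gland. AJ565506 had a difference in week change of -5.30 ± 1.51 (SE), with an adjusted p of 0.013. It was well above background in 2 of 5 control gonads at week 8, so this size rests partly on background. CU991544 rose more in gonad (adjusted p of 2.9e-05), where it was well above background in 0 of 5 controls at week 2 and 5 of 5 at week 8. FP001978 was lower in its week change (adjusted p of 5.3e-05), and was well above background in 0 of 5 control glands at week 2 and 0 of 5 control gonads at week 8. No size is given for these 2 probes, which were at background in those groups. With oyster as a block 7169 probes passed, 3394 higher and 3775 lower. The share of these calls that were higher was 55.3% in the main scaling and 68.3% with normexp, whose median over all tested probes was 0.33 against 0.04.

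Exposure to the beads gave few differences in the gonad. At week 2, 1 of 24619 probes passed and 1050 had an unadjusted p under 0.05 (limma), where 1231 are expected with no difference. FP011244 (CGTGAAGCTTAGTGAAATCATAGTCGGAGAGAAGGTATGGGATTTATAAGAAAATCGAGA) was at least 2.42-fold lower in exposed gonads, with an adjusted p of 0.0026. It was well above background in 4 of 5 control gonads, at -4.21 ± 0.69 (SD, n = 5), and in 0 of 7 exposed gonads, measured at -7.33 ± 0.41. The call was lost with both normexp corrections, with quantile normalization and in the submitters' table. Within day 3, 2 probes passed. CU991217 had the smallest p of the probes higher in exposed gonads, with a difference of 1.75 ± 0.41 (SE), and did not pass (adjusted p of 1.0). The median half-width of the 95% confidence interval was 0.93 log2 per probe.

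At week 8, none of 24619 gonad probes passed with limma, and 2123 had an unadjusted p under 0.05 against 1231 expected. That count was 1159 with normexp, 545 with normexp on all spots, 2054 with quantile scaling and 1759 in the submitters' table. CU684577 (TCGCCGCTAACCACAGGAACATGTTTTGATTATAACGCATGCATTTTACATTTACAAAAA) came nearest among the higher probes, at -0.34 ± 0.43 (SD, n = 8) in exposed and -1.81 ± 0.15 (SD, n = 5) in control gonads, with an adjusted p of 0.075. CU989386 came nearest among the lower ones, with a difference of -2.80 ± 0.50 (SE) and an adjusted p of 0.085, and was well above background in 2 of 8 exposed and 4 of 5 control gonads. Without exposed replicate 34, 104 probes passed. The count was 38 without exposed replicate 25, 4 without control replicate 19 and 2 without exposed replicate 41. Within day 4, with 5 exposed and 3 control gonads, 256 passed, 249 of them higher in exposed gonads. The 3 control arrays of that day were dimmer, with a 75th percentile signal of 190 to 231 against 256 to 412 in the 5 exposed arrays. Over all days 60.4% of probes were well above background in controls and 66.0% in exposed gonads. With day as a term none passed and 1754 had an unadjusted p under 0.05. With the slide as a random block 6 passed. The median half-width of the interval was 0.91 log2.

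The gland-high set mean was -1.89 ± 0.36 (SD, n = 8) in week 8 exposed gonads and -2.32 ± 0.21 (SD, n = 5) in controls. This difference of 0.42 log2 did not pass, with an exact permutation adjusted p of 0.060 (raw p 0.037). The oocyte-high mean was -0.03 ± 0.25 (SD, n = 8) against 0.20 ± 0.29 (SD, n = 5), with an exact permutation adjusted p of 0.21. This difference passed with normexp, with normexp on all spots, in the submitters' table and without slide 2 (exact permutation adjusted p of 0.026, 0.022, 0.020 and 0.043), and did not with quantile normalization or a set minimum of 1 log2 (0.14 and 0.38). The gland-high difference passed without slide 2 and at a set minimum of 1 log2 (0.043 and 0.044). It did not with normexp, normexp on all spots, quantile normalization or the submitters' table (0.21, 0.23, 0.18 and 0.13). No probe of either set passed on its own in this comparison. Camera with the preset correlation gave adjusted p of 7.0e-16 for the gland-high set and 1.4e-16 for the oocyte-high set, with an estimated correlation adjusted p = 0.039 and adjusted p = 0.061, and fry gave adjusted p = 0.035 and adjusted p = 0.14. The estimated correlations were 0.11 and 0.16, far above the preset 0.01, so the preset p are too small. Camera with the preset also passed both sets at week 2 (adjusted p of 3.9e-05 and 0.011), where the permutation tests did not. Within day 4 the differences were 0.49 and -0.35, with exact permutation raw p of 0.14 and 0.054, and with day as a term 0.43 ± 0.20 (SE) and -0.30 ± 0.21. Day 2 held 1 array of each group, too few for a value. At week 2 the differences were 0.06 and -0.25, with exact permutation adjusted p of 0.74 and 0.31, and 0.14 and -0.30 within day 3. The oocyte-high difference at week 2 was -0.10 with normexp, -0.14 in the submitters' table and -0.13 without control 19.

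Exposure gave no call in the digestive gland at either week. At week 2, 0 of 24279 probes passed with limma and 1408 had an unadjusted p under 0.05, where 1214 are expected. That count was 907 with normexp and 9529 with normexp on all spots. FP010664 had a difference of 1.41 ± 0.29 (SE) and AM865430 of -1.10 ± 0.22, both with an adjusted p of 0.61. At week 8, 0 of 24279 passed and 2265 had an unadjusted p under 0.05, or 1461 with normexp and 2714 with normexp on all spots. BG467430 had the smallest p, at -4.18 ± 0.23 (SD, n = 8) in exposed and -2.66 ± 0.77 (SD, n = 6) in control glands, with an adjusted p of 0.26. AM864207 was well above background in 6 of 8 exposed and 0 of 6 control glands. Its mean on these arrays was at least 2.74-fold higher in the exposed, a difference that did not pass (adjusted p of 0.42). Within day 3 the week 2 comparison gave 3 probes, and the week 8 comparison gave 18 within day 2 and 3 within day 4. With day as a term none passed at either week, and 1928 and 1913 probes had an unadjusted p under 0.05. The median half-widths of the intervals were 0.81 and 0.75 log2.

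In oocytes, 0 of 19290 probes passed between exposed and control females with limma, and 1503 had an unadjusted p under 0.05 against 964 expected. AM860203 was well above background in 3 of 3 exposed and 0 of 5 control samples. Its mean on these arrays was at least 4.07-fold higher in the exposed, a difference that did not pass (adjusted p of 0.62). AM865922 was at -1.25 ± 0.06 (SD, n = 3) in exposed and 0.87 ± 0.48 (SD, n = 5) in control oocytes, also with an adjusted p of 0.62. All oocyte arrays were scanned on day 5, on 3 slides that each held both groups, and with the slide as a block none passed and 1533 had an unadjusted p under 0.05. Normexp on all spots gave 2879 at that level. The median half-width of the interval was 0.94 log2.

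**Figure D2:**
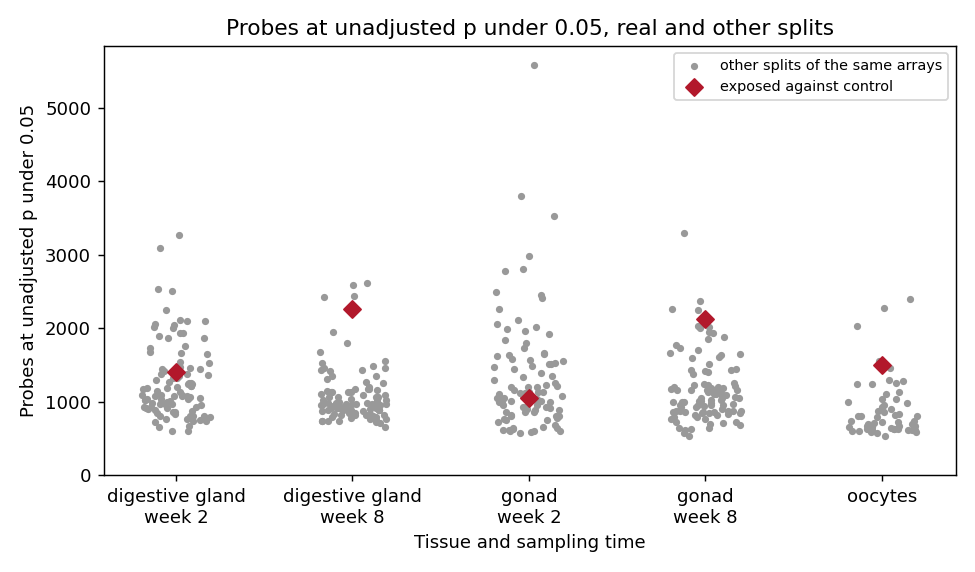
Number of probes at an unadjusted p under 0.05 for exposed against control oysters (red diamonds) and for other splits of the same arrays into groups of the same sizes (grey points), in each tissue and week. The real counts, 1408, 2265, 1050, 2123 and 1503 from left to right, lie inside the range of the other splits, whose highest counts are 3270, 2620, 5591, 3295 and 2392.

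The effect of exposure did not differ detectably between the weeks. With limma 0 of 24279 probes passed in the digestive gland and 0 of 24619 in the gonad, with 2113 and 1662 at an unadjusted p under 0.05, or 1502 and 967 with normexp and 822 and 652 with normexp on all spots. No scan day held all 4 groups of either test, and with day as a term none passed, with 2937 and 1291 at an unadjusted p under 0.05. Between the tissues, the fit with oyster as a block keeps the pairing. It gave 0 probes at week 2 and 5 at week 8, all of them with a higher effect in gonad (limma). At an unadjusted p under 0.05 it gave 788 and 2632, and the medians over other splits of the oysters in that fit were 1447 and 974. Chance was not excluded for these counts, as given below. The fit without a block, which ignores the pairing, gave 0 of 26645 probes at week 2 and at week 8. It had 296 and 1153 at an unadjusted p under 0.05 (limma), and the medians over other splits in that fit were 537 and 365. Without a block, the counts at an unadjusted p under 0.05 were 168 and 450 with normexp, and 2057 and 474 with normexp on all spots. With day as a term none passed, with 452 and 1238 at an unadjusted p under 0.05. Within day 4 the week 8 difference gave 132 probes, and day 2 held 1 exposed and 1 control gonad, too few for a value. Within day 3 the week 2 difference gave none, with 963 at that level.

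Both tissues of an oyster deviated together from their groups. Over 16248 probes, the deviations of digestive gland and gonad arrays from their group means had a mean correlation across probes of 0.67 in the 4 same-oyster pairs on 1 slide, 0.57 in the 10 pairs of 1 day on different slides and 0.51 in the 11 pairs of different days. Pairs of different oysters had means of 0.06, -0.02 and -0.03. Probes are not independent replicates, and these values compare arrays.

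**Figure D3:**
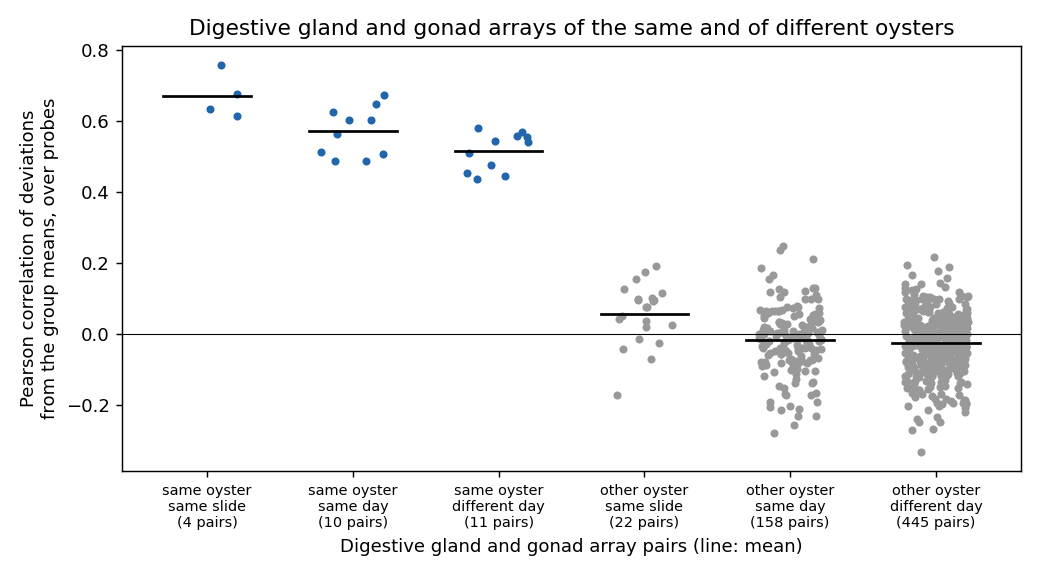
Pearson correlation across probes of the deviations from the group means, for each pair of a digestive gland and a gonad array, by oyster and by shared slide or scan day (black lines: means). The 25 same-oyster pairs lie between 0.44 and 0.76, and pairs of different oysters on different days reach at most 0.22.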

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

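The set means, the 3 added comparisons and the tests of scan day on control gonads, of array brightness, of shared slides and of splits with the oyster block were chosen after the results were seen.

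The week change of the controls differed between the tissues for 3635 probes, by the test of the difference itself. For this count 1 of 100 splits of the oysters gave as many, the real one, and the highest other gave 3095, so chance is excluded at this level. With oyster as a block it was also 1 of 100 (7169, highest other 6203). How many oysters kept their own week in the splits with the highest other counts was not examined, so no other structure of the samples can be read from them.

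Of 125 groups of arrays examined, 8 held an array far from the others, where chance gives about 6.25. The oocyte-high mean of exposed week 2 digestive gland replicate 44 was -1.86, and the next was -1.66. CU998573 stood at -0.83 in week 8 control gonad replicate 19, above -6.29 for the next. CU991908 stood at -4.87 in exposed week 8 digestive gland replicate 35, below 0.04 for the next, at -3.52 in exposed week 2 gonad replicate 25, above -6.96, and at -5.80 in week 2 control gonad replicate 19, above -7.28. CU991544 stood at -0.92 in week 8 control gonad replicate 11, below 0.94, and at -5.82 in the digestive gland of week 8 control replicate 11, below -3.06. FP001978 stood at -4.86 in week 8 control digestive gland replicate 1, below -2.21.

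For the week change of the gonad, the first pattern weighed, chance is excluded at this level: 1 of 100 splits gave as many probes in controls (6996, next 2698) and 1 of 100 in exposed gonads (7215, next 61). The count in controls after quantile normalization was 0.983 of the main count, which argues against scaling by the 75th percentile as the source of the number of calls. A count says little on direction, which moved with the processing. The share of control calls that rose was 47.8% in the main scaling, 53.7% after quantile normalization and 63.8% with normexp. Within scan day 4, a share of 0.937 of the probes called over all exposed gonads kept at least 0.5 of their change. The day 4 arrays were among those that chose these probes, so this share is partly fixed by the choice. Tested within that day alone 1322 probes passed, which argues against day as the whole source in exposed gonads. In control gonads the changes of the set means with day as a term were 1.24 ± 0.30 (SE) and -1.32 ± 0.29, which argues against day as their whole source, while for single probes a share of 0.235 of the count was left, with a median size of 0.838 times and a wider SE, so day cannot be told apart from week for the rest. The stage of the reproductive cycle, which the design varies with the week, stays open and was not tested.

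The second is the gland-high set in week 8 gonads, whose difference of 0.42 log2 between exposed and control did not pass (exact permutation adjusted p = 0.060), but passed without slide 2, without exposed 35 or exposed 44, at a set minimum of 1 log2, by camera with an estimated correlation and by fry, with adjusted p of 0.020 to 0.046. It did not pass under the 4 other scalings, with 0.13 to 0.23. Without slide 2 it was 0.484, which argues against that array as its source. Within scan day 4 it was 0.488 ± 0.220 (SE), and with the array's log2 75th percentile signal as a term 0.376 ± 0.160 (SE), both too wide to exclude a part for the day or for brightness. An effect of exposure, which the design names, is what these tests asked about. It did not pass in the main setting and passed in only some of the others, so it stays open and is not established.

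The deviations shared by both tissues of an oyster are the third. Same-oyster pairs scanned on different days correlated at 0.437 or more, which argues against a shared slide or day as the whole source. Over 6736 probes whose level differed by under 0.5 log2 between the tissues, the mean correlation was 0.558. A varying share of 1 tissue in the other would move these probes little, which argues against such a share as the whole source. Material taken with the other tissue would also bring that oyster's own deviations, so this value cannot exclude it. In 12 oysters not used to choose probes, a share of 0.888 of the pair correlation was left without the top 5% of probes, and the chosen 812 probes had a slope of 0.823 of gonad on gland deviations. Both values are consistent with a state of the oyster or its RNA that moves most probes and with fixed differences of like size in both tissues, such as genotype, which these tests do not tell apart.

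For the other comparisons, splits of the same samples were counted on probes at an unadjusted p under 0.05 where no more than 1 probe passed. Chance was not excluded for exposure in the digestive gland at week 2 (30 of 100 splits gave as many as 1408, highest other 3270) and week 8 (5 of 100, 2265, 2620). Nor was it in the gonad at week 2 (57 of 100, 1050, 5591) and week 8 (5 of 100, 2123, 3295), or in oocytes (6 of 56, 1503, 2392). It was not excluded for the change of the effect between weeks in the digestive gland (5 of 100, 2113, 2545) and gonad (16 of 100, 1662, 2593), or for its difference between tissues at week 2 (81 of 100, 296, 2678, and with oyster as a block 84 of 100, 788, 5714). Some of these splits gave several times the real count, and what set them apart was not examined. For the difference between tissues at week 8, 3 of 100 splits gave as many as 1153, with a highest other of 2023. This share is not adjusted over the exposure counts tested here, so chance is not excluded over all of them. The median of the other splits was 365, and the count fell to 450 with normexp. No probe passed on its own without the oyster block. With the block 5 passed, and 3 of 100 splits gave as many (highest other 119). At an unadjusted p under 0.05 the block gave 2632, and 2 of 100 splits gave as many (highest other 4052, median of the others 974). The splits with the block were chosen after the results were seen and are likewise not adjusted, so chance is not excluded there either. What set the split with 119 apart was not examined. On probes past the threshold, chance was excluded for gonad against digestive gland (1 of 100 exchanges of the tissues within oysters, 14009, highest other 9862). It was also excluded for the week change of the digestive gland in controls (1 of 100, 85, 6) and exposed oysters (1 of 100, 254, 13).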

How the results depend on the processing

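Signal over background limits the results: dim probes carry background, and normexp and the submitters' table gave smaller changes for the week 2 gonad call. That call was also lost with quantile normalization, which starts from the same background-subtracted signal as the main setting. The tests with normexp without background-marked spots, the submitters' table, scan day, the omission of slide 2, the lower set minimum, the added comparisons and the set means were chosen after the data were seen. Normexp on all spots, the planned correction, was spoiled on several arrays and its values are given first. The gene list tests were not run. Where no construction is named, the cause was not tested.

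With normexp on all spots, exposure gave 1 call in the digestive gland at week 2 and 1 at week 8, and 0 in gonads at week 2. The week change gave 26 in control glands, 2 in exposed glands, 4140 in control gonads and 3868 in exposed gonads, and 2168 for its difference between the tissues. The oocyte-high difference at week 2 turned to 0.085, AM865430 in week 2 glands turned to 0.71 and AM860203 in oocytes turned to -0.094, none past the threshold. The week 8 oocyte-high difference was -0.35 (exact permutation adjusted p = 0.022).

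Under the other alternatives, single arrays left out and fits within single scan days aside, no call was gained or lost for exposure in the digestive gland at both weeks, in oocytes, for the change of the effect between weeks in both tissues, or for its difference between tissues at week 2. The 1 call of exposure in week 2 gonads became 0 with normexp, quantile normalization and the submitters' table. The 0 of week 8 gonads became 6 with slide as a random block, 3 with array weights and 1 with only the 2 groups compared. The 0 for the difference of the effect between tissues at week 8 became 3 with quantile normalization, 3 with array weights and 5 with the oyster block. The 3635 for the week change between tissues became 7169 with the oyster block, and the block gave 16716 for gonad against digestive gland.

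The 85 of the week change of control glands became 37 with normexp, 5 with scan day as a term, 22 with only the 2 groups compared and 47 without slide 2. The 254 of exposed glands became 168 with normexp, 168 without the filter, 153 with slide as a random block, 86 with scan day as a term and 696 with array weights. The 6996 of control gonads became 1641 with scan day as a term.

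Numbers shared over the weeks or over the oocyte groups marked no pairing: same-numbered arrays of the weeks had a mean r of -0.04 (14 pairs, -0.25 to 0.15) and those of oocytes 0.01 (2 pairs). A block by number gave 1 and 54 in control glands and gonads, 0 and 32 in exposed glands and gonads, and 0 in oocytes.

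Leaving out single arrays gave 0 to 1 for exposure in week 2 glands (1 without exposed 43), 0 to 3 in week 8 glands (3 without control 17, 1 without control 19) and 1 to 2 in week 2 gonads (2 without control 17). It gave 0 to 104 in week 8 gonads (104 without exposed 34, 38 without exposed 25, 4 without control 19, 2 without exposed 41) and 0 to 2 in oocytes (2 without control 3, 1 without exposed 1). For the change of the effect between weeks in gonad it gave 0 to 6 (6 without week 8 exposed 34, 1 without week 2 control 17). For its difference between tissues at week 8 it gave 0 to 12 (without gonad exposed 34 it was 12, without 25 it was 8, and 1 each without 28, 41 and gland control 19).

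For the week change of control glands it gave 47 to 131 (47 without week 2 control 17, 53 without 1 and 54 without 2, and 47 without week 8 control 1 and 131 without 11). For exposed glands it gave 118 to 592: without week 2 exposed 25, 37 and 41 it was 138, 155 and 148, and without week 8 exposed 25, 27, 28, 33, 34, 35, 41 and 44 it was 140, 592, 149, 125, 118, 152, 147 and 135. It gave 5661 to 7020 in control gonads, 6362 to 7540 in exposed gonads, 2856 to 4161 for the difference between tissues and 13747 to 14074 for gonad against digestive gland.

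In week 8 gonads the oocyte-high difference was -0.31 with normexp (adjusted p = 0.026), -0.29 in the submitters' table (adjusted p = 0.020) and -0.34 without slide 2, whose gonad array is control 1 (adjusted p = 0.043), and -0.34 to -0.16 without single arrays. The gland-high difference was 0.36 at a set minimum of 1 log2 (adjusted p = 0.044), 0.48 without slide 2 (adjusted p = 0.043), 0.47 without exposed 35 and 0.50 without exposed 44 (adjusted p = 0.046 and adjusted p = 0.020), and 0.34 to 0.50 without single arrays. The week 2 oocyte-high difference was -0.33 to -0.13 without single arrays. At week 2 the gland-high difference turned to -0.0040 without exposed 44, -0.016 without control 1 and -0.022 without control 19, with a highest of 0.16. These p are from exact permutation tests. Of 340 values of named probes under other settings, 283 stayed on their side of the threshold, 52 lost and 3 gained a call, and 2 turned.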

Other observations

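The probes higher in exposed week 8 gonads without exposed replicate 34 (98 probes) and within scan day 4 (249 probes) shared 76. Of the 98, 11 were in the gland-high set and 2 in the oocyte-high set, and of the 249, 13 and 6, where 17.2% of the tested probes were gland-high. Both lists were chosen after the values were seen and hold most of the same arrays. Replicate 34 was scanned on day 2.

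The 2 arrays of slide 2, both tissues of week 8 control oyster 1 and the only arrays of scan day 1, lay at -133 and -138 on the third principal component, where the week 8 control means were -42.8 in digestive gland and -63.4 in gonad. The oyster, the slide and the day are the same for these arrays.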
